A study of Mus musculus with 4 samples.

How the data were processed

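Total RNA of E14tg2a embryonic stem cells was purified with a PureLink kit and labelled with biotin by a whole-transcript terminal labelling kit, per the labels' protocols, and measured on GeneAtlas arrays. The 4 arrays, of wild type and Ctbp1/2 double-knockout cells at d0 and d2, were all on strip 2, so the strip does not separate the groups. The value table deposited by the authors holds log2 values made with RMA, per the submitters' processing notes, which name no version. RMA corrects background, normalizes between arrays by quantiles and summarizes probes per probe set. Most values lie between 0 and 1, which is unusual for RMA output, so whether the table is plain RMA output stays open. The log base is not written in the table and is taken as log2, RMA's usual base; a difference of 1 is called 2-fold on that assumption, and every fold given here depends on it. Whether the 4 arrays were normalized together with other arrays of the series is not given in the sources used here. The column medians were 0.354 (WT d0), 0.367 (WT d2), 0.365 (DKO d0) and 0.412 (DKO d2), the lowest values between -1.11 and -0.88 and the highest near 12.2. These medians differ, so the probe-set values themselves are not quantile-normalized across the columns. Since RMA normalizes probes before it summarizes them, this does not show whether the 4 arrays were normalized together. The table was used as deposited, with no further scaling.

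Of the 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none. Genes were named only from probe sets with 1 symbol, updated by Entrez number through the RefSeq gene table of GRCm38.p6, where 23328 matched; the table was used for names alone, since no genome build is stated for the arrays, and no coordinates are given. Each gene was represented by its probe set with the highest mean over the 4 arrays, which was a choice among several for 1082 of 22180 genes. Genes whose highest value was below the 40th percentile of all values (0.30) were left out, which left 20015 genes.

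Between single arrays the log2 difference was computed, and genes with a difference of at least 1 either way (2-fold) were counted; such differences have no error and no test. The changes shared by both genotypes, and the genotype differences shared by both days, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, genotype and day as additive terms, 1 residual degree of freedom, prior degrees of freedom 7.21), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A true difference between genotypes in the d2 change adds to the error of this fit. The limma step was tested on simulated values for the d2 change over 20015 genes with Gaussian noise of a median SD of 0.18: it recovered 45 of 50 genes changed by 1 and 50 of 50 changed by 2, 3 or 4, with 31 false calls among the unchanged genes and 3 false calls when nothing was changed. The 31 false calls were a larger share of all calls than 0.05. Simulated noise had the same SD for genes of like expression, unlike the data. The recovery therefore does not carry over to the results below.

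Before the data were examined, 30 lists of pluripotency, lineage, signalling, metabolic and stress genes were fixed, holding 474 genes, of which 437 matched a gene of the array and 410 were counted. A list's median difference was set against 10000 random lists of the same size, drawn from the same 20 bins of mean expression; its percentile describes these arrays and is no test of the conditions. The rule for named genes was fixed then too. It took the design genes, up to 4 members per list and the 12 largest differences each way per comparison. From the largest differences it left out predicted genes, olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs. For response sizes, DKO changes were shuffled 1000 times among genes of the same expression bin. Exact binomial intervals used scipy 1.17.1, with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and figures matplotlib 3.10.9.

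Alternatives were equal array medians, quantile normalization, cyclic loess, no filter on dim probe sets, a stricter filter at the 60th percentile (0.46), the mean of a gene's probe sets, a 1.5-fold threshold, moderation without trend, robust moderation and an adjusted p under 0.1. Counting only protein-coding genes other than olfactory and vomeronasal receptors, and the alternatives of the overlap between comparisons, were added after the data were seen. Arrays of Suz12-knockout cells were not analysed here.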

Results

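Gene expression was measured with 4 Affymetrix GeneAtlas arrays on E14tg2a mouse embryonic stem cells, a feeder-independent line, kept in serum with LIF. The cells were either wild type (WT) or lacked both Ctbp1 and Ctbp2 (double knockout, DKO), a pair of genes for transcriptional corepressors. Each genotype was sampled at d0 and d2, with 1 array per group and no replicates, so differences between single arrays carry no error. The series concerns overexpression of PRDM14, a PR-domain protein of naive pluripotent and germ cells. The labels do not say how or when overexpression was started, and d0 and d2 are read here as days 0 and 2 of it. Suz12-knockout arrays that the series title also names were not analysed here. The median deposited log2 value was 0.35 on the WT d0 array, 0.37 on WT d2, 0.36 on DKO d0 and 0.41 on DKO d2, and between 9.50% and 11.4% of the 41345 probe sets lay above 1. So many values below 1 are unusual for RMA, and the log2 scale, on which a difference of 1 is 2-fold, is assumed. The small number of arrays limits the precision of every value.

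Values of the pluripotency factors Pou5f1, Sox2 and Nanog lay between 0 and 1 on all 4 arrays. In the order WT d0, WT d2, DKO d0 and DKO d2, Pou5f1 (Oct4) measured 0.58, 0.75, 0.62 and 0.51, Sox2 0.62, 0.74, 0.71 and 0.70, and Nanog 0.55, 0.56, 0.76 and 0.39. The housekeeping gene Actb measured 0.40, 0.35, 0.55 and -0.06, and Gapdh 5.94, 5.76, 5.93 and 6.25. The mitochondrially encoded ND6, a subunit of respiratory complex I, measured 8.14, 7.99, 7.98 and 8.14 and was named after its values were seen. Levels of different probe sets also depend on their probes, so these values do not order the genes by abundance. A value below 0.30, the level of the filter on dim probe sets, is not shown to be above background. Many of the differences named below are set against such a value, and their size and rank are uncertain. Examples are Twf1, Dppa5a and Cdh2 on DKO d2, Tmem92, Tcstv3, Dsg1a and Prps1 on WT d0, Kir3dl1 on WT d2 and Oas1e on DKO d0.

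**Figure D1:**
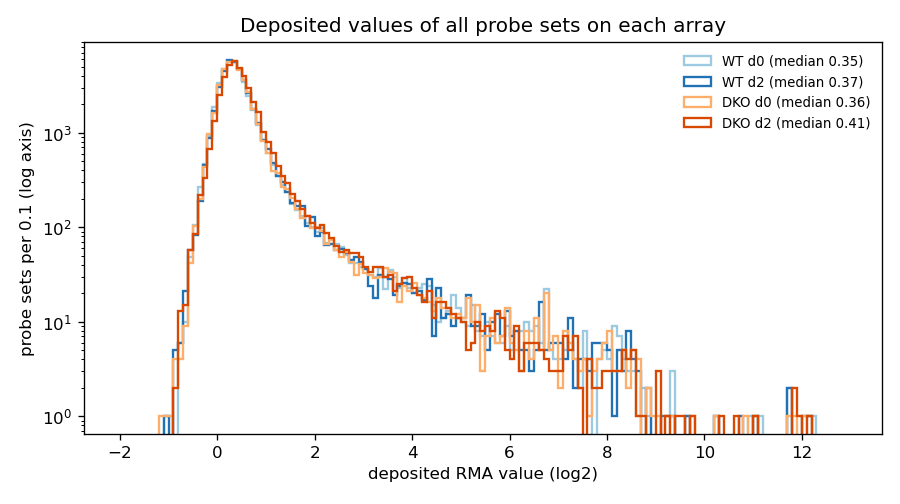
Deposited RMA value (log2, horizontal axis) against the number of probe sets per bin (log axis) for each of the 4 arrays. Most probe sets lie between 0 and 1 on every array, with medians from 0.35 to 0.41 and maxima near 12.2.

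The genes named by the design were read first, as a check of the labels. Prdm14 measured 0.34 on WT d0 and 0.42 on WT d2, and 0.24 on DKO d0 and 0.68 on DKO d2. It was higher at d2 in both genotypes, but limma's estimate of the shared change was 0.26 with a standard error of 0.16 and an adjusted p of 0.923. Ctbp1 measured 0.63 and 0.32 on the WT arrays and 0.56 and 0.42 on the DKO arrays, and Ctbp2 measured 0.55 and 0.46 against 0.55 and 0.42. The limma genotype estimate was 0.0099 for Ctbp1 (adjusted p 0.997) and -0.02 for Ctbp2 (adjusted p 0.995). The labels do not say which part of either gene was deleted, and a probe set outside that part checks nothing. Suz12, a core PRC2 subunit, measured 0.54, 0.29, 0.26 and 0.31 in the order WT d0, WT d2, DKO d0 and DKO d2, and Cbfa2t2, a corepressor that binds PRDM14, 0.54, 0.45, 0.53 and 0.33. Neither the overexpression nor the knockout could be read from its own gene, so WT, DKO, d0 and d2 stand throughout for arrays labelled so, and every direction below rests on those labels.

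**Figure D2:**
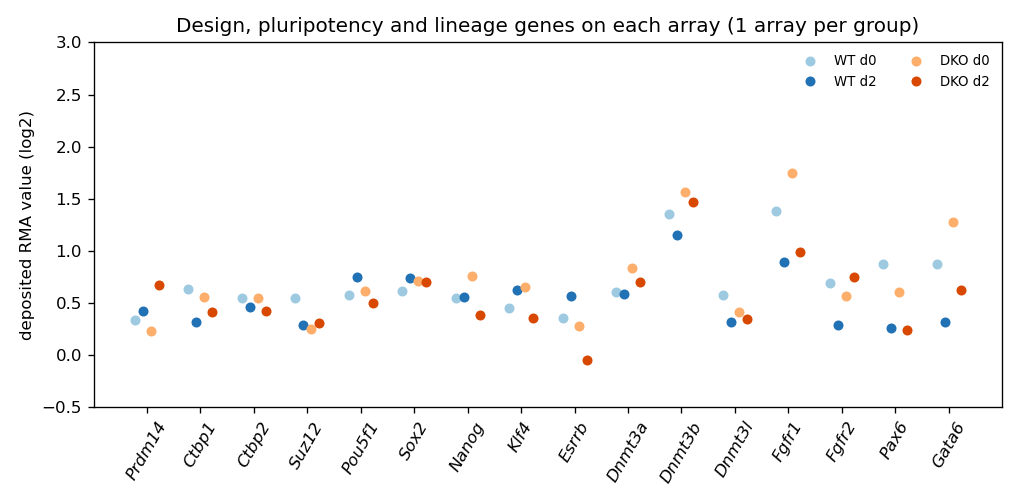
Deposited RMA value (log2, vertical axis) of design, pluripotency, DNA methyltransferase, FGF receptor and lineage genes, 1 point per array. Pou5f1 lies between 0.51 and 0.75, Prdm14 between 0.24 and 0.68, and Fgfr1 between 0.90 and 1.75.

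The first comparison set d2 against d0 in WT cells, read as the time of PRDM14 overexpression. No array is labelled as d2 without overexpression, so an effect of PRDM14 cannot be told apart from that of time in culture. Ighg3, an immunoglobulin heavy-chain constant region, had the largest positive difference among the named genes, from 1.53 at d0 to 3.87 at d2 (2.34). Dcpp2 was higher by 1.93, the desmosomal cadherin Dsg1a by 1.81, the deubiquitinase gene Usp17la by 1.51 and Nkd1, a WNT pathway inhibitor, by 1.35. Prps1, which makes phosphoribosyl pyrophosphate, was higher by 1.35 and Cox5b, a subunit of cytochrome c oxidase, by 1.27. On the lower side, the killer-cell receptor gene Kir3dl1 differed by -1.39, Mcfd2, a partner of a cargo receptor between ER and Golgi, by -1.20, the neuronal calcium sensor Vsnl1 by -1.19, the histone gene H2ac1 by -1.16 and the stress-response gene Osgin1 by -1.11.

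Across the 20015 genes counted, 39 were higher and 32 lower at d2 by at least 2-fold in WT. The other named genes were Ttc30a2, Bex2, Swsap1, Hsd3b6 and Glipr1l1 (1.27 to 1.44) and Ftl1-ps2, Serpina3i, Ang6, Sez6l2, Sult2a3, Slc22a13b and Colgalt1 (-1.21 to -1.08). Values of pluripotency genes differed little. Of 18 counted naive genes 11 were above 0 and none reached 2-fold, with Tcl1 at -0.42 and Dppa3 at -0.29. Of 12 core genes 4 were above 0, with Lin28a at 0.46 and Dppa4 at 0.38. The median level was 0.53 for the naive and 0.40 for the core list, against 0.40 for protein-coding genes. Signal over background could not be measured, so these values do not show that pluripotency genes were unchanged. Of 20 FGF receptors and ERK targets 8 were above 0, with Etv4 at -0.61, Fgfr1 at -0.49, Fgfr2 at -0.41 and Dusp5 at 0.33. Dnmt1, the maintenance methyltransferase, was higher by 0.73 and Dnmt3l, a cofactor of de novo methylation, differed by -0.26. The glycolysis list had a median of -0.18, at percentile 1.5 of 10000 random lists matched on expression, with 3 of 13 members above 0 and Ldha at -0.45. The other 29 lists lay within the middle 95% of random lists. Nkd1 was the 1 list member of 410 that passed 2-fold. Where a gene's probe sets were averaged, the WT difference of Cox5b was 0.35, that of Ighg3 1.21, that of Swsap1 0.51 and that of Sez6l2 -0.47.

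The same interval was then compared in DKO cells, with the same limit. Rhoa, a small GTPase of the actin cytoskeleton, was higher at d2 by 2.16 and Ighg3 by 2.13, from 1.71 to 3.85. Pmaip1, the proapoptotic BH3-only gene also called Noxa, was higher by 1.70, Oas1e of the oligoadenylate synthetase family by 1.51, and the cornified envelope genes Lce3c and Flg by 1.47 and 1.43. The translation helicase gene Eif4a2 went from 7.14 to 3.04 (-4.10) and Twf1, an actin monomer-binding protein, from 3.40 to 0.21 (-3.19). The ribosomal gene Rpl13 differed by -1.91, the heterochromatin protein gene Cbx3 by -1.73, Ahcy, which clears S-adenosylhomocysteine, by -1.72 and the proteasome gene Psmb1 by -1.69.

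In total 124 genes were higher and 73 lower by at least 2-fold in DKO, a split of 99 and 90 with the array medians set equal, 103 and 90 after quantile normalization and 105 and 78 after cyclic loess. The other named genes were Speer4b, Rps15, Gast, Rpl34, Gstm1 and Spopfm2 (1.41 to 1.63) and Rps12-ps24, Rsph3b, Tcstv3, Tlcd1, Ifna4 and Tmem92 (-2.14 to -1.49). Dppa5a, a naive pluripotency marker, differed by -1.22 and N-cadherin, Cdh2, by -1.17. Of the 18 naive genes 8 were above 0, and of the 12 core genes 4, with Lin28a at 0.83. Of the 20 FGF receptors and ERK targets 9 were above 0, with Fgfr1 at -0.76, Dusp6 at -0.47, Spry2 at 0.44 and Spred2 at 0.41. In the 2-cell-like list Tcstv3 differed by -1.68 and Tmem92 by -1.49, while Zscan4c was higher by 1.03. The values of Tcstv3 and Tmem92 were highest on DKO d0, at 1.68 and 2.14. Their differences from WT at d0 and between genotypes use the same DKO d0 values, so they are not separate observations. The mesendoderm list had a median of -0.15 (percentile 2.42, Msgn1 at -0.57) and the proliferation list -0.13 (percentile 2.27, Cdc20 at -0.41), and the other 28 lists lay within the middle 95% of random lists.

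The DKO d2 array correlated less with the other 3 arrays than they did with each other. Its Pearson correlation with each of them across probe sets was 0.727, where the other pairs gave 0.827 to 0.832. Spearman correlations were lower, at 0.472 to 0.479 with this array and 0.555 to 0.577 for the other pairs. Probe sets are not independent replicates. On 332 probe sets it lay at least 1 beyond the other arrays while those spanned at most 0.5, against 82 for WT d0, 101 for WT d2 and 87 for DKO d0. Olfactory and vomeronasal receptor genes, a class chosen after the values were seen, passed 2-fold in 2.09% of cases in DKO d2 against d0 and in 0.950% in WT, other coding genes in 0.749% and 0.235%, and all genes in 0.984% and 0.355%. Averaging a gene's probe sets gave -1.30 for Eif4a2, 0.64 for Rhoa, 0.94 for Ighg3, -0.63 for Rpl13, -0.64 for Cbx3, -0.94 for Ahcy and -0.68 for Tlcd1.

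Few genes moved the same way in both genotypes. Ighg3, Cox5b, the ribosomal gene Rps15 and 1700029P11Rik were higher by at least 2-fold in both, where independent lists would share 0.242, and the microRNA genes Mir328 and Mir466h were lower in both, where 0.117 would be shared. The chance values for all genes treat every gene as equally likely to pass. Among the 221 genes with a mean above 2, 2 were higher in both, where 0.380 would be shared. In the same 221 genes 1 was lower in both, where 0.452 would be. Mir328 differed by -1.25 in WT and -2.03 in DKO, and Mir466h by -1.28 and -2.35. With the probe sets of each gene averaged, Rps15, Mir328 and Mir466h passed in both genotypes and Ighg3, Cox5b and 1700029P11Rik did not, which left 1 higher gene where 0.166 would be shared and 2 lower genes where 0.0978 would be. In the deposited values no gene passed 2-fold in opposite directions (0.340 by chance), against 1 with equal medians and 2 after quantile normalization. 1700029P11Rik and both microRNA genes lie outside the rule for named genes and were named after their values were seen. Across the 20015 genes the WT and DKO changes had a Pearson correlation of 0.031 and a Spearman correlation of 0.025. Among the 221 genes with a mean above 2 these were 0.133 and -0.002. With 1 array per group a low correlation does not show that the genotypes respond differently, and genes are not independent replicates.

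The shared d2 change was tested with limma in an additive model whose error is the departure from additivity, on 1 residual degree of freedom. No gene passed an adjusted p of 0.05 in limma, where the lowest adjusted p was 0.923. At an unadjusted p under 0.05 limma gave 1031 genes (5.15%), where 1000.8 would arise by chance. The 12 lowest unadjusted values included those of Kir3dl1 (-1.08 ± 0.18 SE), Ighg3 (2.24 ± 0.38 SE), Sult2a3 (-0.93 ± 0.17 SE) and Cox5b (1.31 ± 0.25 SE), each with a limma adjusted p of 0.923. Of the 410 list members 22 had an unadjusted limma p under 0.05, and 0 passed when adjusted over the list alone, in each of the 30 lists. Setting the array medians equal gave 11 limma calls and the stricter filter on dim probe sets 12.

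**Figure D3:**
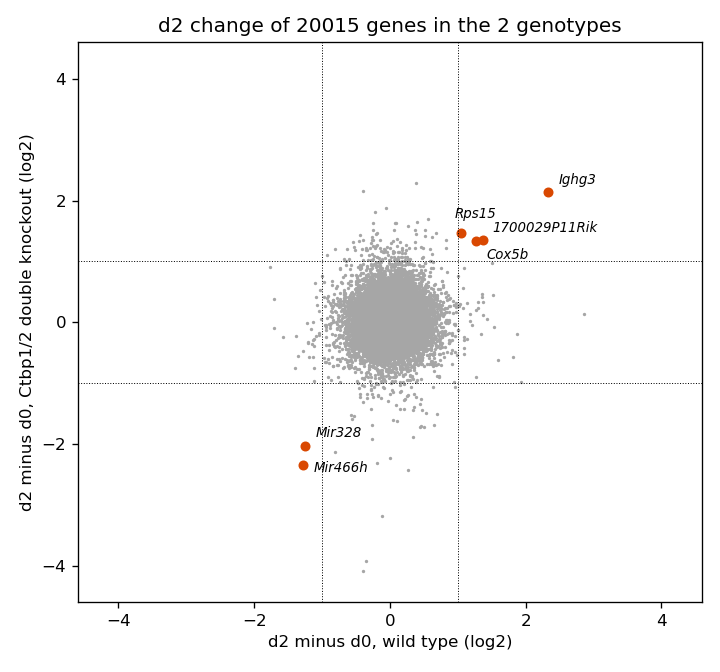
Difference d2 minus d0 (log2) in WT (horizontal axis) and DKO (vertical axis), 1 grey point per gene, with dotted lines at 2-fold. The 6 genes past 2-fold in both genotypes are marked, of which 3 pass when the probe sets of a gene are averaged; the correlation across the 20015 genes was 0.031.

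Whether the d2 change differed between genotypes was given per gene as the DKO change minus the WT change, a difference without a test. Olfactory and vomeronasal receptors and predicted genes are left out of the named genes. Among the named genes the largest positive values were those of Rhoa (2.55), the melanocortin receptor gene Mc5r (2.01), Flg (1.87), Rps26 (1.85) and Speer4a (1.80). The largest negative values among them were those of Eif4a2 (-3.71), Twf1 (-3.08), Dcpp2 (-2.91), Dsg1a (-2.38), Tcstv3 (-2.33), Ahcy (-2.22), Glipr1l1 (-2.18) and Cbx3 (-2.18). In total 271 genes were higher and 220 lower by at least 2-fold, a split of 223 and 252 with equal medians, 216 and 258 after quantile normalization and 225 and 246 after cyclic loess. This difference combines all 4 arrays, DKO d2 among them, and its robust SD over genes was 0.36. The d2 changes had 0.24 in WT and 0.28 in DKO. The same cutoff lets more genes pass where the spread is wider, so these counts cannot be set against those of the d2 changes. The other named genes were Tesk1, Dmrtc2, Lce3c, Rpl34, Pramel20, Nans and H4f16 (1.62 to 1.76) and Rsph3b, Tmem92, Phf11a and Tnnt1 (-2.17 to -1.78).

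Among list members 9 of 410 passed 2-fold in this difference, a share close to that of all genes (491 of 20015, 2.45%). From the 2-cell-like list these were Tcstv1 (1.25), Pramel16 (1.57), Tcstv3 and Tmem92. The others were Cdh2 (-1.18), the WNT inhibitor Dkk1 (1.01), Bmp8b (1.46), the VEGF receptor gene Kdr (-1.05) and the polarity gene Crb3 (1.05). None of the 30 lists left the middle 95% of random lists. Response sizes were compared on the 29 genes whose mean change over both genotypes was at least 2-fold. The 14 higher genes had a median change of 0.83 in WT and 1.43 in DKO, and the 15 lower genes -0.54 and -2.14. The change was smaller in DKO for 6 of the 29 (20.7%). Choosing genes on the mean favours the genotype with the wider differences, here DKO: with DKO changes shuffled among genes of like expression, the median share over 1000 shuffles was 26.3% (middle 95% 13.3% to 40.9%), so the observed share does not stand apart from unrelated changes. Averaging probe sets gave -1.34 for Eif4a2, 0.88 for Rhoa, 1.04 for Rps26, -1.12 for Ahcy, -0.72 for Cbx3, 1.02 for Nans and 0.81 for H4f16.

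DKO was also compared with WT at d0, read here as before overexpression. Tmem92 and Tcstv3, transcripts of 2-cell-like cells, were higher in DKO by 2.09 and 1.61, with WT values of 0.05 and 0.07. Cbx3 was higher by 1.52, Tcl1b3 by 1.30, the phosphatase subunit Ppp2cb by 1.27, the cytokine receptor chain Csf2rb by 1.09 and the alpha-tubulin gene Tuba1c by 1.04. Trim43c, of a tripartite motif family, went from 4.48 in WT to 2.49 in DKO (-1.98), the serpin gene Serpina3i differed by -1.42, Calm5 by -1.29, the hair keratin gene Krt31 by -1.26 and the kinase gene Tesk1 by -1.18.

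At d0, 35 genes were higher and 36 lower in DKO by at least 2-fold. The other named genes were Speer4f1, Myct1, Rpl9, Snx20 and Tagln2 (1.06 to 1.25) and Fbxw22, Slc22a13b, Rpl34, Pramel20, Anapc15, Erlin2 and Snhg9 (-1.33 to -1.10). Serpina3i and Slc22a13b were also among the lower genes of WT d2 against d0, which shares the WT d0 array. Cdh2 was higher by 1.02. Cdh2 and Cbx3 were lower in DKO d2 against d0, which uses the same DKO d0 values, so these are not separate observations. Of the 22 counted 2-cell-like genes Tmem92 and Tcstv3 passed 2-fold, while Zscan4a differed by -0.72 and Tcstv1 by -0.65, and of the 18 naive genes 10 were above 0, with Tfcp2l1 at 0.47 and Dppa3 at -0.49. The PRC2 subunit Aebp2 was higher by 0.49 and Epop differed by -0.38. The BMP target list had a median of 0.20 (percentile 98.0), with 6 of 9 members above 0 and Msx2 at 0.48, and the other 29 lists lay within the middle 95% of random lists. Averaging probe sets gave 0.30 for Cbx3, 0.43 for Rpl9, 0.48 for Tagln2 and 0.31 for Tuba1c.

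At d2, Rhoa was higher in DKO by 2.70, Rps26 by 1.99, Lce3c by 1.62, Mc5r by 1.58, Flg by 1.57, the phosphomannomutase gene Pmm1 by 1.43, Vsnl1 by 1.42 and the mitochondrial ribosomal gene Mrpl23 by 1.37. Eif4a2 differed by -3.71, Twf1 by -3.34, Trim43c by -2.22, Dcpp2 by -2.10, Dsg1a by -2.08, Rpl13 by -1.83 and Ighm, the immunoglobulin mu constant region, by -1.62. Rhoa, Lce3c, Flg, Eif4a2, Twf1 and Rpl13 were also named in DKO d2 against d0, which uses the same DKO d2 values. Dcpp2 and Dsg1a were named in WT d2 against d0, which uses the same WT d2 values. These repeats, and those in the difference between genotypes, are not separate observations. In total 110 genes were higher and 83 lower, a split of 93 and 94 with equal medians, 91 and 87 after quantile normalization and 98 and 84 after cyclic loess. The other named genes were Speer4a, H2aw, Cend1 and Inpp1 (1.33 to 1.70) and Tlcd1, Phf11a, Serp2, Csprs and Rps12-ps24 (-1.99 to -1.47). Pramel16 was the 1 list member past 2-fold (1.07). Esrrb, a naive pluripotency factor, differed by -0.61, Dppa5a by -0.71 and Lin28a by 0.75, and of the 5 genes for DNA methyltransferases and their cofactors Dnmt3b was higher by 0.32 and Dnmt1 differed by -0.31. None of the 30 lists left the middle 95% of random lists. This comparison uses the DKO d2 array, and receptor genes passed 2-fold in 2.75% of cases here against 0.665% at d0, and other coding genes in 0.700% against 0.254%. Averaging probe sets gave -1.15 for Eif4a2, 0.92 for Rhoa, 1.19 for Rps26, 0.62 for Cend1, -1.05 for Tlcd1, -0.71 for Rpl13, -0.91 for Csprs and -0.36 for Ighm.

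Calm5 and Trim43c, with the microRNA genes Mir328 and Mirlet7a-1, were lower in DKO by at least 2-fold on both days, where independent lists would share 0.149. That chance value treats every gene as equally likely to pass. All 4 lie among the 221 genes with a mean above 2, where 1.05 would be shared. Calm5 differed by -1.29 at d0 and -1.0 at d2, Trim43c by -1.98 and -2.22, Mir328 by -2.13 and -2.91 and Mirlet7a-1 by -1.17 and -1.82; the microRNA genes were named after their values were seen. In the deposited values no gene was higher on both days, and Olfr417 and Rsph3b passed 2-fold in opposite directions, where 0.343 would by chance. After cyclic loess Calm5 was no longer among the lower genes, and after cyclic loess or quantile normalization Lce3d was higher on both days and 3 genes passed in opposite directions. The differences at d0 and d2 had a Pearson correlation of 0.021 across genes, and of 0.150 (Spearman 0.043) among the 221 genes with a mean above 2. In limma's additive fit no gene passed an adjusted p of 0.05 for the genotype difference, where the lowest adjusted p was 0.943. At an unadjusted p under 0.05 limma gave 984 genes (4.92%) against 1000.8 by chance. The lowest values belonged to Serpina3i (-1.14 ± 0.18 SE), Nhlrc1 (-0.96 ± 0.16 SE), Mir328 (-2.52 ± 0.42 SE) and Trim43c (-2.10 ± 0.40 SE), each with a limma adjusted p of 0.943. Of the 410 list members 19 had an unadjusted limma p under 0.05 and 0 passed when adjusted over the list alone, in each of the 30 lists. Setting the array medians equal gave 4 limma calls and the stricter filter 6. Usp17, Speer4, Trim43, Pramel, Dcpp, Tcstv and ribosomal protein genes have close copies, so their values are uncertain as those of single genes.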

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

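A genotype difference past 2-fold on both days with opposite signs drew attention to a pair of genes. Olfr417, an olfactory receptor gene, differed between DKO and WT by -1.60 at d0 and by 1.07 at d2, an opposite direction that was not tested. Rsph3b, a radial spoke gene, differed by 1.0 at d0 and by -1.17 at d2, which was not tested either.

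The comparisons of the report leave out probe sets without a single gene name. At d2, 1162 of 15220 of these passed 2-fold in WT and 1737 in DKO, against 73 and 206 of 21144 probe sets with 1 gene symbol. Most 2-fold differences thus lay outside the genes counted. Among the 15220, 103 were higher at d2 by at least 2-fold in both genotypes, where independent lists would share 37.9. Another 112 were lower in both, where 28.6 would be shared. A further 193 passed 2-fold in opposite directions, where 66.1 would by chance, so opposite changes exceeded chance too, and the correlation of the changes across these probe sets was 0.014. The counts therefore do not show a shared d2 change.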

How the results depend on the processing

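The coding-gene count and the alternatives of the overlap between comparisons were added after the data were seen. Alternative gene values were computed for the design genes and the 12 largest differences each way per comparison, and not for other list members. Of these, 548 lay within the robust SD of their comparison over all genes (0.24 to 0.36) of the deposited value. The other 32 moved farther, nearly all where a gene's probe sets were averaged, as in Eif4a2, Rhoa and Cox5b. Averaging cannot move a gene with 1 probe set, and only 1082 of 22180 genes had several. Equal medians shift all genes of an array by the same small amount. The count of 548 therefore does not show that the named differences are stable. For list medians 586 lay within the SD of matched random lists and 14 moved farther. The sign changed for 83 of the 600 list values, all of medians within 0.074 of 0. It also changed for 6 of the 580 gene values, all of design genes within 0.021 of 0. Among the values computed, no gene difference past 2-fold and no list outside the middle 95% of random lists changed sign. At 1.5-fold the counts were 678 (WT d2 against d0), 1226 (DKO d2 against d0), 676 (DKO against WT at d0), 1231 (DKO against WT at d2) and 2656 (difference between genotypes), since the threshold is lower. Among coding genes without receptors they were 38, 121, 41, 113 and 315, since fewer genes are counted. The other alternatives kept these 5 counts within 1.5 times. For the shared d2 change limma called 11 genes with equal medians, 1 after quantile normalization, 1 after cyclic loess and 12 under the stricter filter, against 0 as deposited; for the genotype difference it called 4, 1, 1 and 6. The prior degrees of freedom were 7.21 as deposited and 28.0, 24.0, 20.9 and 30.2 in those settings; the cause was not tested further. No filter, averaged probe sets, either other moderation and an adjusted p under 0.1 gave 0 for both. Kir3dl1 was called for d2 in 4 of 9 settings (limma adjusted p from 0.0085 to 0.930) and Serpina3i for genotype in 4 of 9 (0.0036 to 0.954). The genes past 2-fold at d2 in both genotypes numbered 6 as deposited and 3 with the mean of a gene's probe sets, since Ighg3, Cox5b and 1700029P11Rik then fell short. The correlation of the d2 changes lay between 0.024 and 0.033 and the share of genes with the smaller change in DKO between 19.2% and 24.0%. No paired analysis by replicate number was possible because each group has 1 array; the additive limma fit already compares the days within genotype. Leaving out an array leaves limma no residual degree of freedom, so no such value was computed, and the comparisons with the DKO d2 array cannot be made without it. Most probe sets lay between 0 and 1, and with no background value or detection call in the table, signal over background could not be measured.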

Other observations

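Other gene groups had single members that differed without passing 2-fold. The Hox list had Hoxc4 higher by 0.95 and Hoxb1 at -0.60 in DKO d2 against d0, with no member past 2-fold. Among germline genes normally silenced by DNA methylation, Asz1 differed by -0.90 at d2 in WT and Rpl10l was higher by 0.72 at d2 in DKO. Fibroblast and feeder markers showed no member past 2-fold in any comparison. At d2 the largest difference was that of Col1a2 in WT (-0.51) and that of Col3a1 in DKO (-0.53). Other members went the other way, with 5 of 11 above 0 in WT and 6 of 11 in DKO. The primitive endoderm factor Gata6 differed by -0.55 in WT and -0.65 in DKO at d2. Over the 30 lists, medians ran from -0.18 (glycolysis) to 0.09 (mesenchymal) for WT d2 against d0 and from -0.15 (mesendoderm) to 0.12 (integrated stress response) for DKO d2 against d0. They ran from -0.09 (neuroectoderm) to 0.20 (BMP targets) for DKO against WT at d0 and from -0.13 (mesendoderm) to 0.14 (2-cell-like) at d2. Of 210 list and result pairs, 4 left the middle 95% of random lists, fewer than chance alone would leave out.

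Identical values recurred on every array. The most repeated value occurred on 120 probe sets of WT d0, 126 of WT d2, 156 of DKO d0 and 203 of DKO d2, and between 1870 and 2307 probe sets per array shared their value with at least 9 others. Among probe sets without a single gene name, 205 had a range above 4 over the 4 arrays; their d2 changes had the same sign in both genotypes for 102 and opposite signs for 103.

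All tests in the paragraphs that follow were chosen after the results were seen. In the first pattern, the design genes and Pou5f1, Sox2 and Nanog had values between 0 and 1, as most probe sets did. A scramble of values over all probe sets is argued against by the mitochondrially encoded genes, of which 9 of 10 lay in the top 10% (exact 95% interval 55.5% to 99.7%), where a scramble would leave about 10%. Of the ribosomal protein genes 38.1% lay there, but of the proteasome subunit genes 10.5%, near the share that a scramble would leave. Values assigned to the wrong probe sets in part are not excluded. Genes of the cells' own programmes differed in median level percentile from those of other lineages by -6.48 points, but probe sets differ in affinity and the bound for this test was set afterwards, so it decides nothing and whether most probe sets lie near background stays open. No biological explanation was tested.

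In the second pattern the DKO d2 array lay apart from the other 3. Receptor genes passed 2-fold 51 times in the comparisons with this array and 17 times in those without it, a ratio of 3 (bootstrap 95% interval 1.67 to 6.50), against 2.71 for other genes. The class was chosen after these counts were seen and its genes have low values, so the ratio decides neither for an array-wide technical difference nor against a response of expressed genes only. With 1 array per group, these explanations cannot be told apart for this array.

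In the third pattern Tmem92 and Tcstv3 were higher on the DKO d0 array. More 2-cell-like cells in that culture may explain it, but the other 20 counted members had a median of 0.02 (bootstrap 95% interval -0.19 to 0.20), at percentile 58.7 of random lists, with 10 above 0 and Zscan4a and Tcstv1 at -0.72 and -0.65; members that go both ways give this explanation no support and do not exclude it. Single-array noise stays open because its test turned on the criterion: 2 or more members higher by at least 1 occurred in 0.13% of random lists, above a bound of 0.0333% for 150 list and comparison pairs, while the criterion used first, 2 members as high as the lower of the pair, occurred in 0 of 10000. Both tests had other criteria at first, by which each counted against its explanation, and were changed after those results, the test of 2-cell-like cells more than once. The explanations cannot be told apart here.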
